A study of Rhagoletis pomonella with 6 samples.

How the data were processed

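The series holds 24 two-colour Agilent arrays of whole Rhagoletis pomonella pupae, on 6 slides of 4 arrays scanned on 2 days, slides 1 to 3 on the first and slides 4 to 6 on the second. Per the labels, total RNA of single pupae was extracted and 325 ng per pupa was amplified and labelled with Cy3 or Cy5, and each pupa was hybridized on up to 3 arrays, each in another comparison. Each comparison had 4 arrays, 2 in each dye orientation and 2 on each scan day. The labels put early-diapause individual 1 on both Cy5 arrays of its comparison, so that 23 individuals were named where 4 at each of 6 time points had been planned.

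The intensity values, per the file headers, are the mean brightness and the median local background of each spot in each channel as extracted by Agilent Feature Extraction 10.1.1.1, with no normalization. Per the file headers, the deposited processed intensity had been background-subtracted, detrended and dye-normalized within each array by the same software. Other deposited columns hold flags of 0 or 1 per spot for signal well above background, saturation and uneven spots. The authors deposited a table of values for 21847 spots, 1 log2 value per comparison, for which the submitters' processing notes name limma, with its version, background correction and normalization not given in the sources used here. Against the ratios computed here (later over earlier), the authors' deposited log2 values correlated across 20881 probes at -0.966 to -0.989 with slopes of -1.08 to -1.13, so they are log2 ratios of the earlier over the later time point. Their medians were 0.0042, -0.0515, -0.0299, 0.008, -0.0198 and -0.023 in the order of the comparisons in the report, and their centring stays unknown. All probes called here that have a value in that table show the same change there.

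Background was corrected with limma's normexp on the mean and background intensities with an offset of 50. Each array was normalized by loess with control spots at weight 0, and control spots were then left out. Spots marked as uneven, 0.043% to 3.13% of an array, were set to missing. At most 2 spots of an array were saturated, and these were kept. Log2 ratios of replicate spots of a probe were averaged, and every ratio was turned to later over earlier. A probe was kept if it was well above background on all 4 arrays in the channel of at least 1 time point of at least 1 comparison, which left 35463 of 43623 probes (81.3%). The fit had 1 coefficient for each of the 6 comparisons and 1 for the dye over all 24 arrays, with lmFit and eBayes in limma 3.58.1 under R 4.3.3, read with the data.table package (version 1.17.8). It had 17 residual and 2.62 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the probes tested, and probes with an adjusted p under 0.05 were called. The fit shares 1 estimate of spread per probe over the comparisons, and pupae that appear in several comparisons were treated there as independent. A target is 1 name in the files, usually with 3 probes, of which a pair lies on 1 strand and 1 probe on the other. Strands were read from the sequences: of 28240 pairs from different sets of the array design, 2180 shared 20 bases as reverse complements and 26 on the same strand, and of 14751 pairs within a set 12014 shared 20 bases on the same strand and 1 as reverse complements. Pairs that share no 20 bases were assigned by set. Which strand is the transcribed one was not known. Figures and a search for peptide motifs used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

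The time course was tested with limma's moderated F test on single-channel log2 intensities, normalized by loess within and Aquantile between arrays. The arrays of a pupa were averaged to 1 value, with the dye as a covariate, so the replicates were the 23 named pupae. The levels given per time point are these values, as mean ± SD over pupae. The 4 arrays of a comparison held different pupae by the labels, except the repeated early-diapause individual.

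Groups, tests, filters, alternatives and the rule for named genes were fixed before the data were examined. That rule and the 21 gene lists needed gene names. The files do not pair targets with names, and 0 of 14760 target names matched a reference of 25184 named genes. Identifiers of the FlyBase form, held by 173 targets, were not traced to genes. The gene lists, the tissue marker lists and the 4 alternatives on them could thus not be run as planned. The rule was applied to targets in place of genes: per comparison, the brightest probe of each target, an adjusted p under 0.05, 1 sign on all 4 arrays, and then the 2 highest and 2 lowest log2 ratios. Where none passed, the 2 probes with the smallest p in each direction were taken. The number of named targets was lowered to 2 per direction after the missing names were known.

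The fit and the F test were checked on simulated arrays with 200 of 35463 probes changed by known amounts. From early to late diapause, 28 of 67 probes changed by a log2 of 1.0 were called and 59 of 66 changed by 2.0, with 2 unchanged probes called. Over the time course 24 of 67 and 53 of 66 were called, with 4 unchanged ones. The alternatives were other background corrections, median centring, scale normalization, other probe filters, no dye term, slide as a random block, the slides of 1 scan day alone, the 4 arrays of a comparison alone, a time-point model, single-channel values per pupa, and each array left out in turn.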

Results

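Gene expression was measured in whole pupae of the apple maggot fly, Rhagoletis pomonella, as the pupae left diapause, the programmed arrest in which this fly spends the winter. Pupae from hawthorn fruit were held at 4 °C for 20 weeks and then warmed to 24 °C, and their metabolic rate was followed. RNA came from single pupae at 6 time points. Early diapause was sampled 24 h after warming and late diapause after 2 weeks of warmth with a flat metabolic rate. The next samples were taken 24 h and 48 h into the first metabolic rise, defined by a gain of at least 40% over a day. The plateau was sampled 5 to 7 days after respiration had levelled off, and the post-plateau 2 to 3 days into the final, exponential rise. The labels named 23 individuals, 3 in early diapause and 4 at each other time point.

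RNA of 2 pupae, 1 labelled with Cy3 and 1 with Cy5, competed on each of 24 Agilent arrays, 4 for each of 6 pairs of time points, with each dye orientation on 2 of the 4. The arrays carried 43623 probes of 60 nt for 14760 targets, most of them named by contig or sequence read. Another 877 targets had names of another form, and 173 had identifiers of the FlyBase form. The median Cy3 intensity of an array ranged from 169.5 to 364 and the median Cy5 intensity from 187.9 to 558.2. Between 70.1% and 87.3% of Cy3 spots and between 64.9% and 85% of Cy5 spots were well above background. After the filter on dim probes, 35463 probes for 13482 targets were tested. The number of arrays, 4 per comparison, limited the precision, and the median standard error of a log2 ratio was 0.22 in each comparison. All ratios are later over earlier time point, opposite to the authors' deposited table. The files do not pair targets with gene names, so targets are given by their identifiers with the sequence of the probe measured.

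Few probes passed limma's test between the start and the end of 2 weeks of warm diapause (246), and 4720 changed from late diapause to 24 h into the first metabolic rise. No probe passed between 24 h and 48 h into the rise (3630 at an unadjusted p under 0.05). From 48 h to the plateau 7806 probes changed, and from plateau to post-plateau 11663, which is 32.9% of the probes tested.

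**Figure D1:**
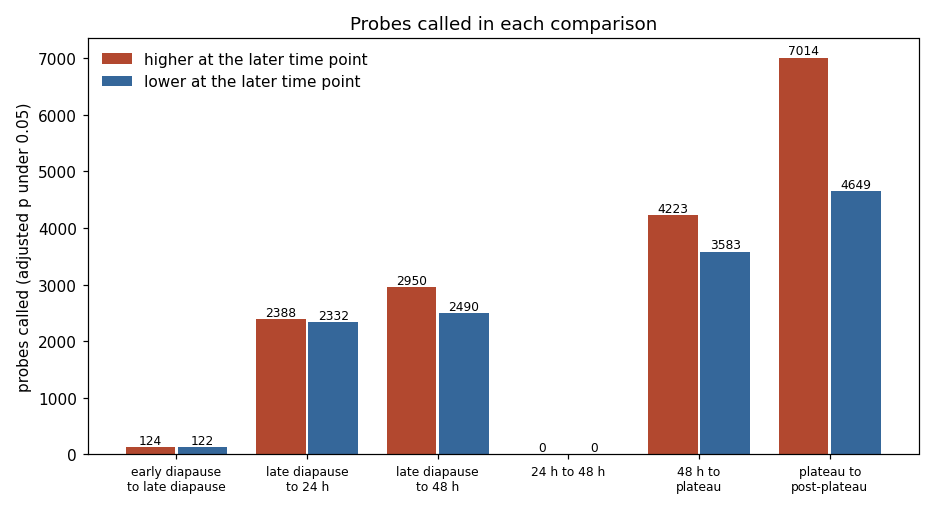
Probes that passed limma's test (adjusted p under 0.05) in each comparison of 4 arrays, with probes higher at the later time point in red and lower ones in blue, on a linear axis from 0. The counts run from 124 higher and 122 lower between early and late diapause, through 0 between 24 h and 48 h, to 7014 higher and 4649 lower from plateau to post-plateau.

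The first comparison asked what changed between the first day of warmth and 2 weeks later, before any metabolic rise. Its 4 arrays held 4 late-diapause pupae but, by the labels, 3 early-diapause pupae, since individual 1 stood on 2 arrays, so an n of 4 counts arrays here and the SE and p take that pupa as 2 replicates. The largest rise among the targets named by the rule was that of contig21057, which was 6.52-fold higher in late diapause (log2 ratio 2.70 ± 0.47 SE, n = 4 arrays, adjusted p = 0.0126). The read EUA37Q301DGXHC was 4.14-fold higher (2.05 ± 0.39 SE, n = 4 arrays, adjusted p = 0.0167). The target contig22568 was lower in late diapause, with a log2 ratio of -2.74 ± 0.51 (SE, n = 4 arrays, adjusted p = 0.0167), and contig15855 was lower with -1.79 ± 0.36 (SE, n = 4 arrays, adjusted p = 0.0234). On 1 value per pupa none of these 4 passed limma's test, with adjusted p of 0.0787, 0.0768, 0.0503 and 0.0835 in the same order, and with the arrays of the repeated individual averaged contig21057 and contig15855 did not (adjusted p = 0.0592 and 0.103). In single pupae the level of contig22568 was 16.08 ± 0.32 log2 units in early diapause (SD, n = 3) and 13.38 ± 0.66 in late diapause (SD, n = 4). Its mean at 48 h into the rise was 16.10 ± 0.85 (SD, n = 4).

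The probe of contig21057 was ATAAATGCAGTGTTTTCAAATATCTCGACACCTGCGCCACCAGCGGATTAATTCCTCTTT and that of EUA37Q301DGXHC was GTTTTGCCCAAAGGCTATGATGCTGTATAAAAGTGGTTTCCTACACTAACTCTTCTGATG. The probe of contig22568 was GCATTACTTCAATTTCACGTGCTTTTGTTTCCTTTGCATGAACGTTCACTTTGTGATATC, and that of contig15855 was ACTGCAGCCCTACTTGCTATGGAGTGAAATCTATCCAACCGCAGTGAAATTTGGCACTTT. A probe for the same strand of EUA37Q301DGXHC gave 2.18 and one for the same strand of contig15855 gave -1.60, with -0.71 from the opposite strand of the latter, and all of these passed. The second probe for the same strand of contig21057 gave 4.10 but did not pass (adjusted p = 0.147), its opposite-strand probe gave 0.31 (adjusted p = 0.765), and the remaining probes of contig22568 gave -0.55 and -0.74 with adjusted p of 0.177 and 0.16.

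In all, 246 of 35463 probes for 184 targets passed limma's test between early and late diapause. Of these 124 were higher and 122 lower, 68 and 36 of them by at least 2-fold, and their median log2 ratios were 1.03 and -0.85. The count fell to 55 with the arrays of the repeated individual averaged, to 29 on 1 value per pupa, and to 0 from the 4 arrays alone (3951 at an unadjusted p under 0.05). It rested on each array: it was 107 without array 1, 55 without array 2, 97 without array 3 and 83 without array 4, and the 4 named targets lost the call in 7 to 9 of the alternative settings each, with adjusted p from 0.00435 to 0.338. Their log2 ratios ranged from 2.26 to 3.03, 1.71 to 2.47, -3.12 to -2.33 and -2.13 to -1.38 over these settings, in the order named. With slide as a random block 728 probes passed, within the slides of the first scan day 0 (4309 at an unadjusted p under 0.05) and within those of the second 39, while centring each array on its median in place of loess left 14.7% of the calls higher against 50.4%, and Agilent's processed signals left 38.7%.

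The second comparison set late diapause against pupae 24 h into the metabolic rise. Among the named targets, EZ4BI6301E26WC was 8.4-fold higher at 24 h (log2 ratio 3.07 ± 0.41 SE, n = 4, adjusted p = 0.000133) and contig13514 was 7.28-fold higher (2.86 ± 0.34 SE, n = 4, adjusted p = 3.82e-05), from a late diapause level that was well above background on 3 of 4 arrays. The read E7OMS0H01BEIWO had a log2 ratio of -4.13 ± 0.53 (SE, n = 4, adjusted p = 7.63e-05), which makes it 17.4-fold lower. The target contig23243 had one of -3.87 ± 0.93 (SE, n = 4, adjusted p = 0.00943). In single pupae, E7OMS0H01BEIWO stood at 12.53 ± 0.55 log2 units in early diapause (SD, n = 3) and 12.35 ± 0.70 in late diapause, and then at 8.26 ± 0.32, 8.39 ± 0.60, 8.34 ± 0.96 and 9.48 ± 0.48 at the 4 later time points (SD, n = 4). The level of EZ4BI6301E26WC was 7.79 ± 0.31 in late diapause, 10.52 ± 0.86 at 24 h and 11.73 ± 0.40 at 48 h (SD, n = 4).

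The probe of EZ4BI6301E26WC was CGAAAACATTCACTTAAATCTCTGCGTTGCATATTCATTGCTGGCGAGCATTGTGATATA, and the remaining probes of this target, which lie on the opposite strand, gave 0.23 and 0.32 and did not pass. The probe of contig13514 was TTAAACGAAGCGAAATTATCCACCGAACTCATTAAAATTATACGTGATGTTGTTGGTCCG, with 2.82 from a further probe for the same strand, which passed, and 0.04 from the opposite strand, which did not (adjusted p = 0.893). The probe of E7OMS0H01BEIWO was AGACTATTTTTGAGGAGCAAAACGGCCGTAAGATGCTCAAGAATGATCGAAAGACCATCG, with -3.94 from a further probe for the same strand, which passed, and -0.37 from the opposite strand, which did not (adjusted p = 0.0702). The probe of contig23243 was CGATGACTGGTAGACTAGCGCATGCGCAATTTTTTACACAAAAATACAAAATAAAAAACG, and a probe for the opposite strand gave 0.15 and did not pass.

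In all, 4720 of 35463 probes (13.3%) for 2781 targets passed limma's test from late diapause to 24 h, 2388 higher and 2332 lower, of which 862 and 832 changed by at least 2-fold. Their median log2 ratios were 0.86 and -0.85. The count was 2284 without array 1, 2371 without array 2 and 2814 without array 4, it was 6192 with slide as a random block, 1375 within the slides of the first scan day and 796 within those of the second, and contig23243 lost the call in 5 of 19 settings, with adjusted p from 0.000842 to 0.154. Over the alternative settings the log2 ratios ranged from 2.41 to 4.05 for EZ4BI6301E26WC, 2.27 to 3.94 for contig13514 (highest with processed signals), -4.57 to -3.72 for E7OMS0H01BEIWO and -4.30 to -3.37 for contig23243, so the folds depend on the processing. From the 4 arrays alone the count was 428, with scale normalization 2638, on 1 value per pupa 2672 and in the time-point model 8044, and median centring made 84.6% of the calls higher in place of 50.6%.

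**Figure D2:**
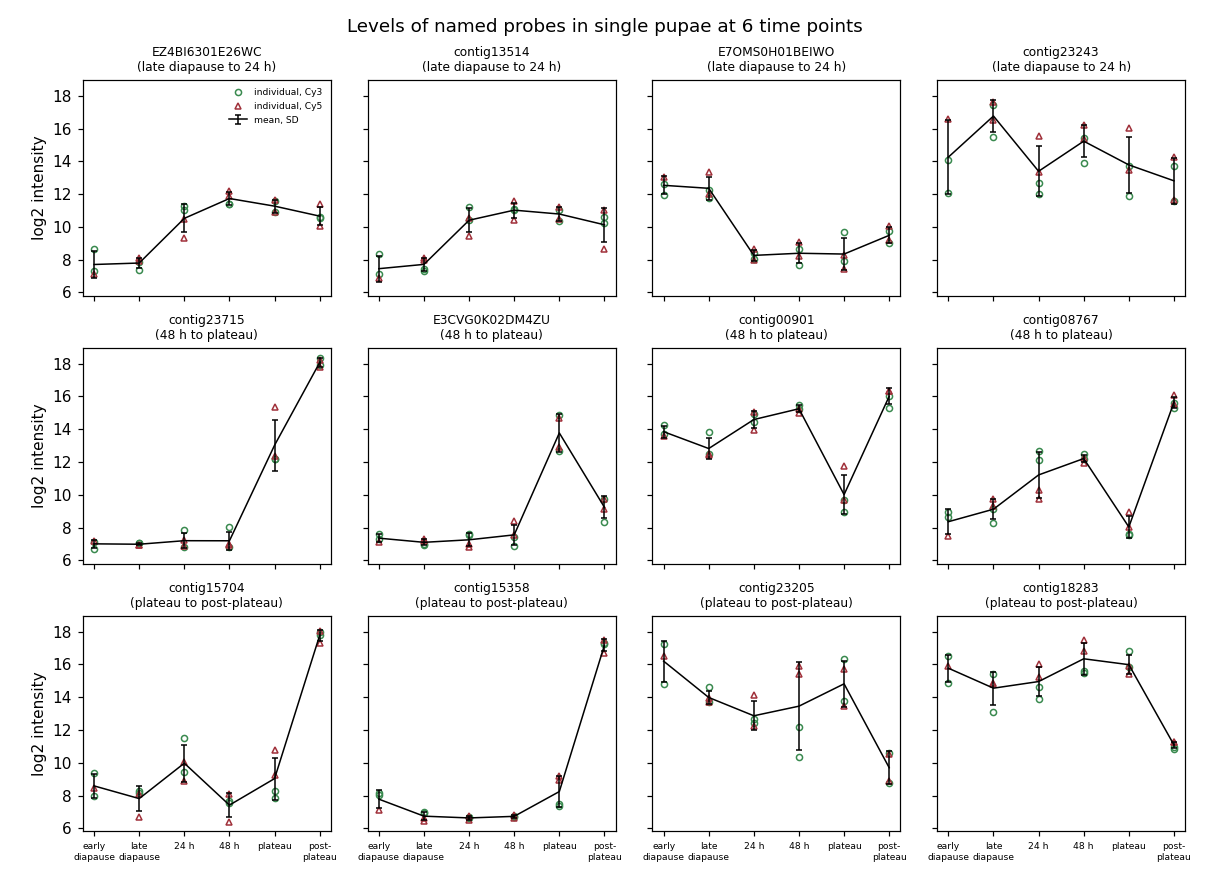
Log2 intensity of 12 named probes in single pupae at the 6 time points, after normalization within and between arrays, with green circles for pupae labelled with Cy3, red triangles for Cy5, and the line and bars for the mean and SD (n = 3 in early diapause, n = 4 at the others). The level of E7OMS0H01BEIWO lies near 12 in diapause and near 8 at 24 h, while contig23715 is near 7 until 48 h and reaches 18.07 in the post-plateau.

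The third comparison set late diapause against 48 h into the rise. The target contig14825 was 11.5-fold higher at 48 h (log2 ratio 3.52 ± 0.56 SE, n = 4, adjusted p = 0.000306) and contig18737 was 10.9-fold higher (3.44 ± 0.75 SE, n = 4, adjusted p = 0.00471). The read E7OMS0H01BEIWO, lower at 24 h, was lower at 48 h as well, with a log2 ratio of -3.77 ± 0.53 (SE, n = 4, adjusted p = 9.6e-05), while its opposite-strand probe gave -0.25 and did not pass (adjusted p = 0.223). The read EZ4BI6301EDXEL had one of -3.76 ± 0.55 (SE, n = 4, adjusted p = 0.000155). In single pupae contig14825 stood at 8.62 ± 0.41 log2 units in late diapause, 10.40 ± 0.45 at 24 h and 12.77 ± 0.99 at 48 h (SD, n = 4). The level of contig18737 was 13.08 ± 0.83 in late diapause and 16.46 ± 0.82 at 48 h, with 9.28 ± 0.54 in the post-plateau (SD, n = 4). In early diapause it was 16.03 ± 1.67 (SD, n = 3), so its level at 48 h was near that of early diapause.

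The probe of contig14825 was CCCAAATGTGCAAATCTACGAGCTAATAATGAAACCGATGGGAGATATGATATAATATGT, and its partner on the same strand passed as well (adjusted p = 0.000324). The probe of contig18737 was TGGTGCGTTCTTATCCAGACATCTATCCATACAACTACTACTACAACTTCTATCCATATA, with 3.30 from its same-strand partner and 1.40 from the opposite strand. The probe of EZ4BI6301EDXEL was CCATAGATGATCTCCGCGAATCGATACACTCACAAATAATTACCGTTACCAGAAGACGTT, with -3.69 from its same-strand partner and -2.63 from the opposite strand. All of these passed the test.

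In all, 5440 of 35462 probes (15.3%) for 3265 targets passed limma's test from late diapause to 48 h, 2950 higher and 2490 lower, with 1141 and 1063 of them changed by at least 2-fold. Their median log2 ratios were 0.88 and -0.91. The count was 2077 without array 1, 3481 without array 3, 3378 without array 4 and 1272 without the arrays of slide 5, 6911 with slide as a random block, 1321 within the slides of the first scan day and 1639 within those of the second, while contig18737 lost the call in 4 of 19 settings (adjusted p from 0.000358 to 0.177) and contig14825 in 1 (3.58e-06 to 0.0726). Log2 ratios ranged from 3.23 to 4.56 for contig14825, 3.03 to 4.15 for contig18737, -4.70 to -2.93 for E7OMS0H01BEIWO and -4.77 to -2.93 for EZ4BI6301EDXEL over the settings. The 4 arrays alone gave 802 and the time-point model 10631, processed signals raised the count to 8321 and median centring to 10746, with 84.1% of the calls higher in place of 54.2%.

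The fourth comparison asked what changed between 24 h and 48 h into the rise. No probe passed limma's test, against 3630 of 35458 at an unadjusted p under 0.05. The targets with the smallest p did not pass: E7OMS0H03GDA55 had a log2 ratio of 1.02 ± 0.17 and contig18127 of 0.74 ± 0.13 (SE, n = 4, adjusted p = 0.0589 for both), and E7OMS0H01CBRBT had -1.27 ± 0.20 and contig05440 -0.80 ± 0.13 (SE, n = 4, adjusted p = 0.0523 for both). All 4 kept 1 sign on the 4 arrays. The level of contig18127 was 12.75 ± 0.11 log2 units at 24 h and 13.54 ± 0.09 at 48 h in single pupae (SD, n = 4), and that of E7OMS0H01CBRBT 11.49 ± 0.45 and 10.28 ± 0.10.

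The probes were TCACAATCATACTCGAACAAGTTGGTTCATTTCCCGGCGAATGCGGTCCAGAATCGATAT for E7OMS0H03GDA55, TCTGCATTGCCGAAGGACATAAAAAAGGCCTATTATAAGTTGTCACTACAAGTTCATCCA for contig18127, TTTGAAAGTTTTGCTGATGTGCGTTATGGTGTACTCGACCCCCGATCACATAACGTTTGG for E7OMS0H01CBRBT and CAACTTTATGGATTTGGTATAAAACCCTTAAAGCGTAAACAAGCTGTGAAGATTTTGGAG for contig05440. Both further probes of contig18127, on either strand, gave 0.75 and 0.70 with adjusted p of 0.0523 and 0.0841. Both further probes of E7OMS0H03GDA55, on the opposite strand, had the other sign, with -0.22 and -0.34 (adjusted p = 0.534 and 0.35). Those of contig05440, also on the opposite strand, gave -0.15 and -0.32 (adjusted p = 0.922 and 0.783). E7OMS0H01CBRBT gave -1.21 on the same strand and -0.57 on the opposite one (adjusted p = 0.0589 and 0.34).

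The count was 0 within the slides of either scan day and in each fit with 1 array left out, and 15 with slide as a random block. A model of the 6 time points over all 24 arrays, which also draws on the indirect path through late diapause and treats arrays that share a pupa as independent, called 350 probes, and scale normalization between arrays called 119. In simulated data with this design, limma called 33 of 67 probes changed by a log2 of 1.0 and 59 of 66 changed by 2.0. Simulated differences of 2-fold were thus found in 49.3% of cases. The noise was drawn apart for each array from the spread shared by all 24 arrays, and 200 of 35463 probes were changed. The share found can therefore differ in the real data, where pupae recur across arrays and more probes may change.

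The fifth comparison followed pupae from 48 h into the rise to the plateau. The target contig23715 was 72.7-fold higher at the plateau (log2 ratio 6.18 ± 0.42 SE, n = 4, adjusted p = 6.96e-09) and E3CVG0K02DM4ZU was 67.7-fold higher (6.08 ± 0.46 SE, n = 4, adjusted p = 2.9e-08). The target contig00901 had a log2 ratio of -5.28 ± 0.49 (SE, n = 4, adjusted p = 5.69e-07), a 38.8-fold lower level, and contig08767 one of -4.94 ± 0.47 (SE, n = 4, adjusted p = 5.13e-07), a 30.7-fold lower level. The levels of the 2 higher targets differed at the next stage: contig23715 stood at 7.19 ± 0.56 at 48 h, 13.02 ± 1.55 at the plateau and 18.07 ± 0.26 in the post-plateau, and E3CVG0K02DM4ZU at 7.55 ± 0.62, 13.77 ± 1.15 and 9.24 ± 0.67 (SD, n = 4). The levels of the 2 lower targets at the plateau lay below those before and after it: contig00901 stood at 15.25 ± 0.21, 10.01 ± 1.21 and 16.01 ± 0.48, and contig08767 at 12.21 ± 0.24, 8.04 ± 0.67 and 15.64 ± 0.34 (SD, n = 4).

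The probe of contig23715 was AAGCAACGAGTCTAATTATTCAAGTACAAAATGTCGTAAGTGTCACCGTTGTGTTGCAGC, with 6.40 from the same-strand partner and 3.00 from the opposite strand. The probe of E3CVG0K02DM4ZU was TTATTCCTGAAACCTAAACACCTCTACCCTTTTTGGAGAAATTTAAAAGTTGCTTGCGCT, and its opposite-strand probes gave 1.29 and 2.65. The probe of contig00901 was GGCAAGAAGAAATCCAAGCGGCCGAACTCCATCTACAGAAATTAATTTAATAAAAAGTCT, with -5.24 from the same-strand partner and -2.72 from the opposite strand. The probe of contig08767 was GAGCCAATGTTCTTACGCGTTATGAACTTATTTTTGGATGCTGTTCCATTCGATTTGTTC, with -5.49 from the same-strand partner, while the opposite strand gave -0.44 and did not pass (adjusted p = 0.0754).

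In all, 7806 of 35463 probes (22%) for 4224 targets passed limma's test from 48 h to the plateau, 4223 higher and 3583 lower, with 1831 and 1522 of them changed by at least 2-fold. Their median log2 ratios were 0.91 and -0.90. The folds moved with the processing: log2 ratios ranged from 4.96 with scale normalization to 7.15 with processed signals for contig23715, and over the settings from 4.85 to 6.62 for E3CVG0K02DM4ZU, -5.90 to -4.20 for contig00901 and -5.62 to -3.92 for contig08767. The count was 5072 without array 2, 9543 with slide as a random block, 4924 within the slides of the first scan day and 2719 within those of the second. It was 1760 from the 4 arrays alone, 4820 with median centring and 3145 with scale normalization between arrays, and the higher majority was lost on 1 value per pupa (2443 higher, 3047 lower) and with probes above background in both channels on all arrays (2976 higher, 3078 lower).

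The sixth comparison followed pupae from the plateau into the final rise. The target contig15704 was 215-fold higher in the post-plateau (log2 ratio 7.75 ± 0.63 SE, n = 4, adjusted p = 1.68e-08) and contig15358 was 200.2-fold higher (7.64 ± 0.35 SE, n = 4, adjusted p = 4.65e-12). Both ratios differed with the dye. With the post-plateau in Cy5 they were 9.35 and 8.94 for contig15704 and 9.07 and 8.59 for contig15358. With it in Cy3 they were 6.80 and 5.90, and 6.62 and 6.30. The SE is taken after the dye term, while the SD over the 4 arrays was 1.66 and 1.39. The target contig23205 was at a 31.9-fold lower level (SE of the log2 ratio 0.80, n = 4, adjusted p = 7.1e-05), and contig18283 had a log2 ratio of -4.91 ± 0.63 (SE, n = 4, adjusted p = 5.42e-06), a 30.1-fold lower level. The level of contig15358 lay between 6.63 and 7.78 log2 units until 48 h, at 8.24 ± 0.95 at the plateau and at 17.17 ± 0.35 in the post-plateau (SD, n = 4). On the arrays shared with the post-plateau alone, the plateau channels averaged 9.53, so the plateau level differed between arrays of the same pupae. The level of contig18283 was 15.98 ± 0.58 at the plateau and 11.09 ± 0.21 in the post-plateau (SD, n = 4).

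The probe of contig15704 was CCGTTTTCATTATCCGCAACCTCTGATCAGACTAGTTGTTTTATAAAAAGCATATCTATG, and the pair on the opposite strand gave 2.26 and 2.35. The probe of contig15358 was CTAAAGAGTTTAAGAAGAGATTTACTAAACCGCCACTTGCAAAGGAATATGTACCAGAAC, with 7.53 from the same-strand partner and 2.45 from the opposite strand. The probe of contig23205 was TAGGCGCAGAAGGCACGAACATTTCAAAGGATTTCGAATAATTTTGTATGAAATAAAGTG, with -5.02 and -1.40. The probe of contig18283 was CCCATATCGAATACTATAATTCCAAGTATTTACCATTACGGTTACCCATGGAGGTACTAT, with -5.02 and -3.23. All of these passed the test, with the smaller change on the opposite strand each time.

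In all, 11663 of 35463 probes (32.9%) for 5884 targets passed limma's test from plateau to post-plateau. Higher probes numbered 7014 and lower ones 4649, with median log2 ratios of 1.26 and -0.71, and among those changed by at least 2-fold 4347 were higher and 1074 lower. The folds moved here too: log2 ratios ranged from 7.11 to 8.74 for contig15704 and 7.01 to 8.93 for contig15358, both highest on 1 value per pupa, and from -5.66 to -4.34 for contig23205 and -5.47 to -4.46 for contig18283. The count was 7266 without array 2, 13221 with slide as a random block, 10069 within the slides of the first scan day, 3228 within those of the second and 4447 from the 4 arrays alone. Median centring turned the split around, with 40.6% of the calls higher in place of 60.1%, and with it the median log2 ratio of the tested probes was -0.16 (-0.02 with loess), while it was -0.11 from early to late diapause, 0.13 from late diapause to 24 h and 0.24 from late diapause to 48 h.

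**Figure D3:**
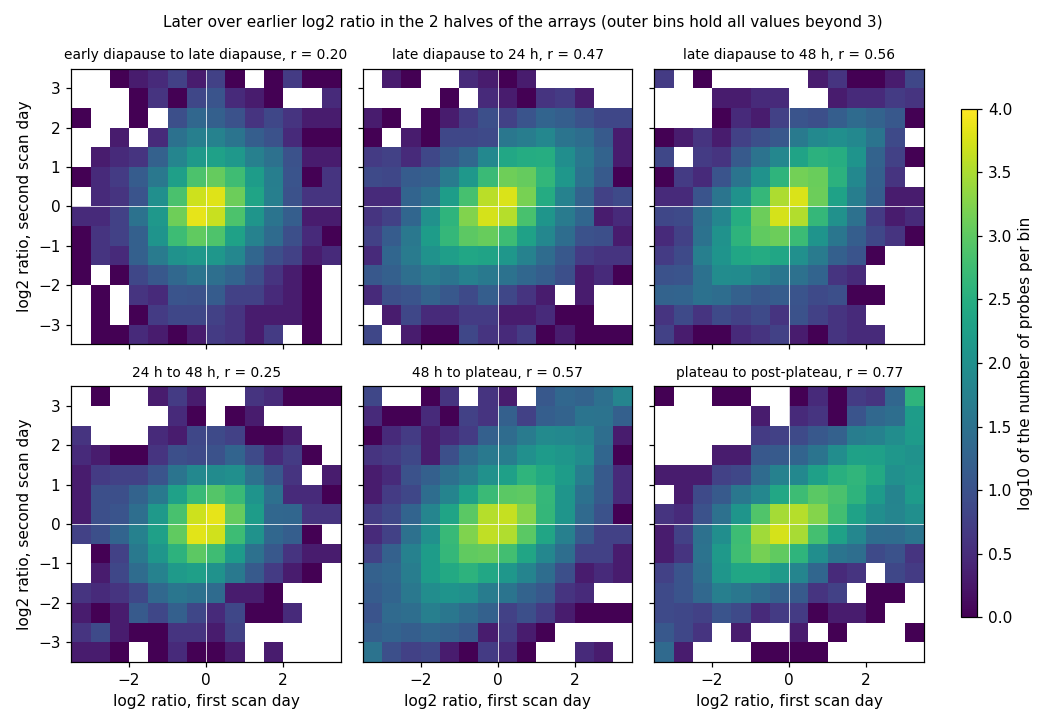
Log2 ratios of all probes in the arrays of the first scan day (x axis) and the second (y axis), which hold different pupae except for the early-diapause individual that the labels name on both days, with colour for the log10 number of probes in each bin of 0.5 log2 units and the outer bins holding all values beyond 3. The correlation across probes runs from 0.20 between early and late diapause and 0.25 from 24 h to 48 h to 0.77 from plateau to post-plateau.

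Within a comparison, the arrays of the first and the second scan day held different pupae by the labels, except that early-diapause individual 1 stood on both days between early and late diapause. Across probes, which are not independent replicates, their log2 ratios correlated with r = 0.202 between early and late diapause, 0.467 from late diapause to 24 h, 0.56 from late diapause to 48 h, 0.246 from 24 h to 48 h, 0.57 from 48 h to plateau and 0.765 from plateau to post-plateau. The share of probes with 1 sign in both sets was 60.1%, 67.7%, 71%, 60%, 65.8% and 74.1% in the same order.

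Over the whole time course, 19741 of 35463 probes (55.7%) differed among the 6 time points by limma's moderated F test on 1 mean value per pupa. The post-plateau stood apart most often: 6025 of these probes (30.5%) had their highest mean level there and 7123 (36.1%) their lowest. The fewest extremes fell at 24 h into the rise, where 1573 probes had their highest and 1143 their lowest level. Late diapause held the highest level of 3789 probes and early diapause that of 3087. At the plateau, more probes had their lowest level (4089) than their highest (3083). These means rest on unequal data. The post-plateau and early diapause had 4 channels each, 24 h and the plateau 8, and late diapause and 48 h 12. A mean from fewer channels varies more and can be an extreme more often, and the share of this in the counts was not tested.

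**Figure D4:**
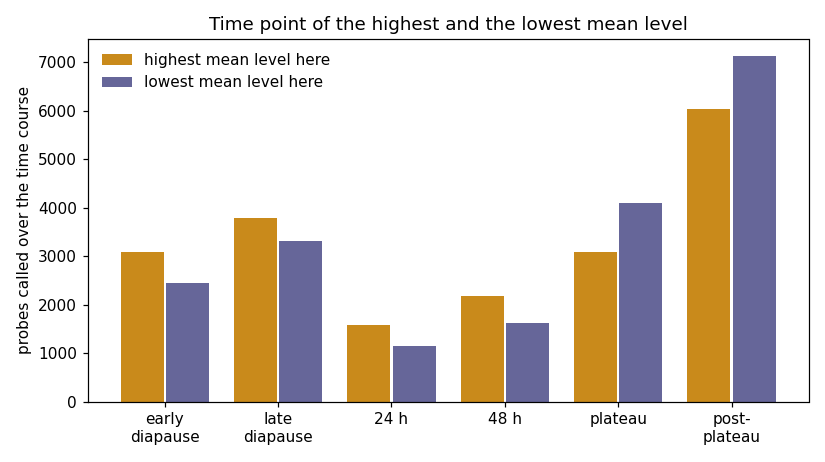
Number of the 19741 probes that differed over the time course whose mean level in single pupae was highest (ochre) or lowest (violet) at each of the 6 time points, on a linear axis from 0. The post-plateau holds the most extremes of both kinds, 6025 and 7123, and 24 h into the rise the fewest, 1573 and 1143.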

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

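The test of median centring for the excess of higher probes in the post-plateau was chosen after the result was seen, and the other tests here were chosen before.

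Of 60 groups of 4 arrays tested, over quality measures and the named ratios, 1 held an array far from the rest, where chance gives about 1 in 20. It was in the median Cy3 intensity of array 4 from late diapause to 24 h, where it was 218.4, while the other arrays of the comparison had 186.5, 189.7 and 191.7. Control spots, which no comparison used, gave a strong signal: the E1A positive-control spots had a median Cy3 intensity of 110300, against 61.1 in negative-control spots.

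No probe was called by limma between 24 h and 48 h into the rise, against 3630 at an unadjusted p under 0.05. Noisier arrays are argued against as the cause, since the median residual SD of the 4 arrays was 0.898 times that of the other 20 arrays. The fit shares 1 spread per probe over all arrays, so the noise of these 4 hardly sets their SE. A spread shared with noisier arrays may itself have hidden changes. The 4 arrays alone gave 0 calls too (3528 at an unadjusted p under 0.05), but from few degrees of freedom. Smaller differences between these time points may account for the lack of calls: the covariance of the log2 ratios between the pupae of the 2 scan days was 0.294 times that from late diapause to 24 h. That ratio is not enough by itself, since early to late diapause had a covariance of 0.05, close to the 0.0543 from 24 h to 48 h, and 246 calls. Small changes stay open too, since limma found 6 of 67 simulated changes of a log2 of 0.5.

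From plateau to post-plateau, 80.2% of the probes called at 2-fold or more were higher. Probes near background were not the whole source, because 2304 of 3200 such probes in the brighter part of the tested probes, or 72%, were higher. The normalization may have made the excess: with median centring in place of loess the share was 42.5%, and with Agilent's processed signals 64.5%. Median centring leaves in a difference between bright and dim probes, which ranged from -2.261 to -0.028 log2 units on single arrays here. It was thus very uneven over the arrays, and how far 1 array made the lower share was not tested. A trend with GC content can be neither excluded nor accepted, since the share was 68.6% after a correction for it, between the bounds set for either outcome, while the median GC content was 41.7% in the higher, the lower and all tested probes alike. A real excess of rising transcripts at this stage stays open and was not tested apart from the normalization.

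The labels name early-diapause individual 1 on 2 arrays, and the early-diapause channels there differed more than those of any pupa measured again. Their deviations from the other arrays correlated at -0.236, while 32 pairs of channels of 1 pupa correlated at 0.558 to 0.933 and 55 pairs of different pupae at -0.604 to -0.254. The SD of the difference was 0.71 against 0.129 to 0.405 within pupae and 0.55 to 0.897 between pupae. After a shift common to the scan days was taken out it was 0.748, within the 0.645 to 0.97 of other time points. That shift was itself a mean of differences between different pupae. All pairs of 1 pupa lay within 1 scan day, while all pairs of different pupae, and the pair in question, lay on different days. These values thus cannot tell 2 different individuals behind 1 label from a difference between scan days. The numbering in the labels goes with 2 individuals. Every other pupa of the first scan day had an even number, and every pupa of the second an odd one. No other pupa stood on both days, and early diapause was the only time point without a number 2. A wrong number on the first day is thus likely, though the labels do not state it. With 2 individuals, early diapause would be a group of 4 pupae.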

How the results depend on the processing

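The settings that kept only the probes of the authors' table and that left out the arrays of slide 5 were chosen after seeing the data. No named target changed sign. The split of calls from plateau to post-plateau turned around with median centring, from 7014 higher and 4649 lower to 5190 and 7607. From 48 h to plateau it did so on 1 value per pupa, from 4223 and 3583 to 2443 and 3047, and with the strict filter, to 2976 and 3078. Of 126 counts under another setting, 73 were within 1.5 times the count reported, 5 of 20 for early to late diapause and 16 of 19 for plateau to post-plateau. Of 452 values of the 24 named results, 391 stayed on their side of the threshold, 43 lost the call and 18 gained one, the last all from 24 h to 48 h. The cause was not tested. The gene list alternatives were not run for lack of gene names, and the authors' deposited values give a correlation and no count. No paired analysis was possible because each group of the labels is 1 comparison, whose 4 ratios already set pupae of both time points against each other on the same array.

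From early to late diapause, counts were 518 with scale normalization, 137 without a dye term, 728 with slide as a random block, 0 and 39 within the slides of each scan day, 0 from the 4 arrays alone (3951 unadjusted), 392 in the time-point model, 29 from single-channel values per pupa, 55 with the arrays of the repeated individual averaged, 138 over the probes of the authors' table and 106 without slide 5. From late diapause to 24 h they were 2638 with scale normalization, 1375 and 796 within scan days, 428 from the 4 arrays alone, 8044 in the time-point model and 2672 from single-channel values. From late diapause to 48 h they were 8321 with processed signals, 10746 with median centring, 1321 and 1639 within scan days, 802 from the 4 arrays alone, 10631 in the time-point model and 1272 without slide 5. From 24 h to 48 h they were 2 with processed signals, 3 without background correction, 1 with median centring, 119 with scale normalization, 5 with no filter, 7 with the strict filter, 15 with slide as a block and 350 in the time-point model. From 48 h to plateau they were 4820 with median centring, 3145 with scale normalization, 4924 and 2719 within scan days, 1760 from the 4 arrays alone and 5181 over the probes of the authors' table. From plateau to post-plateau they were 3228 within the second scan day and 4447 from the 4 arrays alone. The time course gave 13043 with no normalization between arrays.

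With 1 array left out, counts ranged from 55 to 107 for early to late diapause, 2284 to 3453 for late diapause to 24 h, 2077 to 4840 for late diapause to 48 h, 0 to 0 for 24 h to 48 h, 5072 to 6801 for 48 h to plateau and 7266 to 12465 for plateau to post-plateau, and with 1 individual number left out from 13663 to 19237 for the time course. The correlation within slides was 0.129, and that within pupae in the time course 0.8. The time-point model counts arrays of 1 pupa as independent. Signal over background limits the dim probes: 35463 of 43623 could be tested.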

Other observations

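The comparisons of strands, the search for peptide motifs and the view of single targets over all time points were chosen after the results were seen, and so were the overlaps with the step from plateau to post-plateau. The tests of overlap with the step from 48 h to plateau and of other splits of the pupae were chosen before.

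Targets named in 1 comparison had distinct courses over the others. The target contig22568 had 16.08 ± 0.32 log2 units in early diapause (SD, n = 3), 13.38 ± 0.66 in late diapause, 16.10 ± 0.85 at 48 h and 17.78 ± 0.31 in the post-plateau (SD, n = 4). The target contig08767 had 9.12 ± 0.61 in late diapause, 12.21 ± 0.24 at 48 h, 8.04 ± 0.67 at the plateau and 15.64 ± 0.34 in the post-plateau (SD, n = 4). The level of contig21057 was 15.86 ± 0.93 in late diapause and between 13.10 and 14.25 at each other time point. The read EUA37Q301DGXHC stood at 11.24 ± 0.47 in late diapause and 6.73 ± 0.19 in the post-plateau (SD, n = 4).

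A change at the first rise might be undone by the plateau. Of 1398 probes called both from late diapause to 24 h and from 48 h to plateau, against 1039 for independent lists, 53.7% went opposite ways. All lists of a setting came from the same fit, with a spread per probe shared over the comparisons. A probe with a low spread passes more easily in each of them. Joint counts in any direction can thus exceed independent lists without a change that is undone or runs on. The size of this effect was not tested, so no conclusion is drawn from an excess alone. Probes first higher and then lower numbered 493 against 241.3, and those first lower and then higher 258 against 277.7. Probes that went the same way were also above the number for independent lists, with 376 against 284.4 higher both times and 271 against 235.6 lower both times. The opposite share was 60.8% with median centring and 50.8% with processed signals, and the higher-then-lower number was 547 against 258.3 and 414 against 228.1. From late diapause to 48 h and then from plateau to post-plateau, 735 probes were higher and then lower against 386.7, and 420 lower and then higher against 492.5. These were 1213 against 793.2 and 678 against 736 with processed signals. Median centring gave 3887 against 1939.4 and 437 against 249.4, so the second number then lay above that for independent lists. From late diapause to 24 h and then from plateau to post-plateau 45.8% of 1703 went opposite ways, with 460 against 313.1 higher and then lower, 320 against 461.2 lower and then higher, and 418 against 305.7 lower both times. With processed signals the opposite share was 46.2%, but with median centring it was 82.3% of 2243. There 1745 against 874.8 were higher and then lower, and only 96 against 159.2 lower both times. A change during warm diapause that runs on in the step from 48 h to plateau was argued against for most probes called in both: of 109, against 54.1 for independent lists, 37.6% went the same way, although these too exceeded independent lists (23 against 14.8 higher and 18 against 12.3 lower both times). Of 101 probes called from early to late diapause and from plateau to post-plateau, against 80.9, 27 against 24.5 were higher and 32 against 16 lower both times, and 41.6% went opposite ways (19.6% of 92 with median centring). This share and its difference from the earlier step were not tested.

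Probes for opposite strands of a target gave less similar changes than probes for the same strand. From plateau to post-plateau, log2 ratios correlated across probe pairs at 0.982 on the same strand and at 0.572 on opposite strands, a ratio of 0.583. Of 6491 called probes with an opposite-strand partner, 3977 partners were called in the same direction and 71 in the other. Same-strand pairs mostly overlap in sequence and opposite-strand pairs mostly do not, so pairs alike in overlap and in the level of the dimmer probe were also compared. There the ratio was 0.635 without overlap and 0.636 with 20 shared bases, with upper 95% bounds of 0.656 and 0.666. Among pairs with both probes in the brighter part it was 0.769 without overlap and 0.801 with it, and 132 overlapping opposite-strand pairs against 1266 same-strand pairs without overlap gave 0.83. The 0.83 lay between the bounds set for either outcome, so it cannot tell by itself. The pairs alike in overlap and level argue against overlap and dim signal as the whole source of the difference. For opposite-strand probes that follow the same transcript change, a ratio of at least 0.8 over all pairs had been set. The 0.583 over all pairs lay below that bound, and so did the 0.635 and 0.636 in pairs alike in overlap and level. Only the bright overlapping pairs, for which the bound was not set, reached it with 0.801, so the question stays open for such pairs.

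Probes were also grouped by peptide motifs in their open reading frames. After the filter 3 groups had at least 5 members: 37 targets with a nucleotide-binding P-loop, 7 with the active-site histidine of trypsin-like proteases and 6 with the linker between zinc fingers. In 18 tests with limma's camera the smallest p was 0.0283, for the zinc finger linker from plateau to post-plateau (median log2 ratio -0.41), with an adjusted p of 0.509 and a p of 0.0813 with an estimated correlation. No group passed.

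Other splits of the pupae were tested on single-channel values per pupa, with 35 splits for each comparison and 100 for the time course. From late diapause on, except 24 h to 48 h, and over the time course, as many calls came from 1 split, the real one. For a comparison, 1 of 35 is the smallest share these splits can give. Splits that mix time points also hold the real difference in their spread, which lowers their counts. The splits thus argue against chance there without firmly excluding it. The real count and the highest other count were 2672 and 6 for late diapause to 24 h, 5219 and 3 for late diapause to 48 h, 5490 and 42 for 48 h to plateau, 10192 and 2777 for plateau to post-plateau and 19741 and 22 for the time course. From early to late diapause the real grouping gave 29 calls and the highest other split 17. That 1 of 35 splits is the smallest share these splits can give, the count was 0 within the first scan day and from the 4 arrays alone (4309 and 3951 at an unadjusted p under 0.05), and the 4 named targets did not pass in this fit (adjusted p from 0.0503 to 0.0835), so chance is not firmly excluded there. From 24 h to 48 h the real grouping gave 0 calls by limma (2387 at an unadjusted p under 0.05), which all 35 splits must equal or exceed, with 4 in the highest, so the splits say nothing of chance there.

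The direct log2 ratio from late diapause to 48 h and the sum of the ratios from late diapause to 24 h and from 24 h to 48 h correlated at 0.971 across 35458 probes, with a median absolute difference of 0.09. Both were built from the same pupae, so this shows how well arrays repeat on 1 set of pupae and nothing of other pupae. The E1A control spots gave later over earlier log2 ratios after loess of 0.36 ± 0.65 for early to late diapause and -0.76 ± 1.04 for plateau to post-plateau (SD, n = 4), the 2 largest of the 6 comparisons, with a spread larger than the mean. Bright probes minus dim ones differed by 0.63 ± 0.08 from late diapause to 24 h, by 1.02 ± 0.64 from late diapause to 48 h and by -0.76 ± 1.02 from plateau to post-plateau on median-centred arrays (SD, n = 4). From early to late diapause they differed by -0.33 ± 0.175 (SD, n = 4), from -0.474 to -0.079 on single arrays. The values were 0.11 ± 0.21 from 24 h to 48 h and -0.22 ± 0.23 from 48 h to plateau (SD, n = 4). A set of 2631 probes with target names of another form was well above background in 18.5% of channels, against 87.8% for contig probes, and had no value in the authors' deposited table. Of its 462 tested probes, 122 were called from plateau to post-plateau.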
